A study of Mus musculus with 8 samples.

How the data were processed

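Gene expression was measured by sequencing of total RNA from duodenal villus epithelium of male mice on the C57BL/6 (B6) background, in 4 libraries from germ-free animals and 4 libraries from animals born to parents colonised with spore-forming bacteria. Per the labels, villus epithelial cells were captured by laser microdissection from stained frozen sections, RNA was purified on small-volume columns with DNase treatment, and directional libraries were made after depletion of ribosomal RNA. The genotype label carries a different trailing number in each sample, whereas the growth protocol names B6 mice for all of them, and no strain comparison was made.

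The deposited values were raw counts per gene, 1 column per library, for 55416 Ensembl gene identifiers. Per the submitters' processing notes, the tools named were cutadapt 1.16, STAR 2.7.6a, featureCounts 1.6.3 and DESeq2 1.32.0, with the genome build GRCm39. The annotation release, the strand setting and the treatment of reads that match several genes are not given in the sources used here. Counts of near-identical genes and of genes with an antisense partner are therefore uncertain. Symbols were taken from a reference gene table, which matched 52083 of the identifiers. The annotation at hand is for an earlier build, so it was used for names and transcript lengths and no coordinates are given. There were 20074 genes with a count in at least 1 library and 3710 with counts in all 8.

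Counts were filtered with filterByExpr, which kept 9848 genes, and scaled by the trimmed mean of M-values (TMM). The groups were compared with edgeR 4.0.16 in R 4.3.3, by a robust quasi-likelihood fit without covariates and a two-sided test, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are spore-forming against germ-free, on the log2 scale with standard errors (SE). Each SE was taken as the absolute log2 fold change over the square root of the quasi-likelihood F statistic. CPM values of genes are TMM-scaled, while limits for a count of 0 and detection levels are CPM of total counts. A total of 44 gene lists for intestinal function, microbial responses, RNA quality and cell types were fixed before the data were examined. The 39 lists with at least 3 tested members were tested with camera in limma 3.58.1, at a preset correlation of 0.01 between genes, and again with a correlation estimated from the data and with the rotation test fry. Scores of marker and quality lists were means of log2(CPM + 1) per library. Scores and library measures were compared by exact two-sided permutation tests over 70 arrangements, whose smallest possible p is 0.0286.

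The genes named in the text follow a rule fixed before the data were examined. It takes up to 12 genes per direction past the threshold, with groups that do not overlap and a mean of at least 5 CPM in the higher group, the 10 genes with the smallest p where fewer than 10 pass, up to 4 members of each list by p, and the 5 most abundant genes. Because none passed, the 10 with the smallest p are given as values that did not pass. Of the list members, a part is named, and 1 is not reported here.

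A library made from few RNA molecules holds few genes with low counts, because each molecule is copied into many reads. The number of starting molecules was estimated in each library from the abundance, in the other libraries, at which detection was as frequent as non-detection, using genes above 0.5 CPM. Dividing total counts by this estimate gave reads per molecule. Both are estimates that assume the other libraries give the true abundances. Genes detected were also counted after thinning every library to 1342998 counts. A count of 0 was read as up to 3 counts, and such limits cover counting error only, since reads copied from 1 molecule are not independent.

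The fit and list test were tested on simulated counts for the 9848 genes in 4 against 4 libraries, with 50 genes changed at each size. The fit recovered 0 of 50 genes at 2-fold, 2 of 50 at 4-fold, 14 of 50 at 8-fold and 18 of 50 at 16-fold, with 1 false call. Of 76 changed genes with counts in all 8 libraries, 28 were recovered. The spread of each simulated gene was estimated over the 8 libraries without regard to group, so differences between the groups counted as noise. Recovery may therefore be understated. None of the 39 lists was called. The simulated genes varied independently, whereas genes of a real list vary together, so this does not show how often the list test errs on these libraries.

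Alternatives covered other scalings, filters, DESeq2 1.42.0, limma-voom with sample quality weights, a block on the replicate number, removal of mitochondrial, ribosomal RNA and abundant genes, a surrogate variable from sva 3.50.0, and leaving out each library in turn. Other settings, chosen after seeing the data, kept only genes counted in all 8 libraries, left out the libraries with the fewest and the most detected genes, or divided counts by the estimated reads per molecule. Each library was counted as a sample, per the labels. No pair of libraries was as alike as repeated draws of reads from the same library would be, the lowest chi-square per degree of freedom being 39.8, which does not show that they come from separate animals.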

Results

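The comparison asks whether colonisation with a community of spore-forming bacteria alters gene expression in the epithelium of the duodenal villus. Counts per gene were analysed from 8 libraries of villus epithelium, cut by laser capture microdissection from frozen sections 9 µm thick of the duodenum of male mice aged 8 weeks. Of these, 4 came from germ-free mice, which are raised without microbes, and 4 from mice colonised from birth by way of parents carrying spore-forming bacteria. The labels do not state that each library is a separate animal, so p-values measure only the spread between these libraries, which may be technical. Parentage differed together with colonisation, so the comparison covers both. Total counts were 6097578, 3560831, 13047223 and 6050316 in germ-free replicates 1 to 4, and 5222470, 5309681, 1342998 and 4320491 in spore-forming replicates 1 to 4.

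The libraries were rich in transcripts of absorptive and mucus-producing epithelium. The most abundant genes were Mgam, a brush border disaccharidase, at 19955 ± 3751 CPM in germ-free and 19076 ± 6540 CPM in spore-forming libraries (SD, n = 4 each), Fcgbp, a mucus protein, at 18749 ± 8149.5 and 20239 ± 9002 CPM, and Apoa4, an apolipoprotein of chylomicrons, at 20924 ± 6225 and 15930 ± 7019 CPM. Apob, the structural protein of chylomicrons, stood at 14890 ± 3503 and 16824 ± 7457 CPM, and the membrane mucin Muc3 at 12087 ± 807 and 10233 ± 4445 CPM. These 5 levels differed between the groups by less than the SD of at least 1 group.

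Fewer genes had counts in the spore-forming libraries, a difference that did not pass the threshold. Genes with a count numbered 13235 ± 4160 in germ-free and 7937 ± 2225 in spore-forming libraries (SD, n = 4 each; exact permutation p = 0.0571, adjusted 0.126 over 11 library measures). Estimated reads per starting molecule were 21.8, 26.2, 4.91 and 14.0 in germ-free replicates 1 to 4 and 38.2, 43.5, 71.5 and 54.2 in spore-forming replicates 1 to 4, with no overlap and without passing the adjustment (exact permutation p = 0.0286, the smallest this design allows, adjusted 0.126). Spore-forming replicate 3 held counts for 4715 genes and germ-free replicate 3 for 19132. A count of 0 allows up to 0.565 to 2.23 CPM in the spore-forming libraries by reads. With 3 estimated molecules as the limit it allows 21.9, 24.6, 159.8 and 37.6 CPM in spore-forming replicates 1 to 4 and 10.7, 22.05, 1.13 and 6.96 CPM in germ-free replicates 1 to 4, so these limits overlap between the groups.

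**Figure D1:**
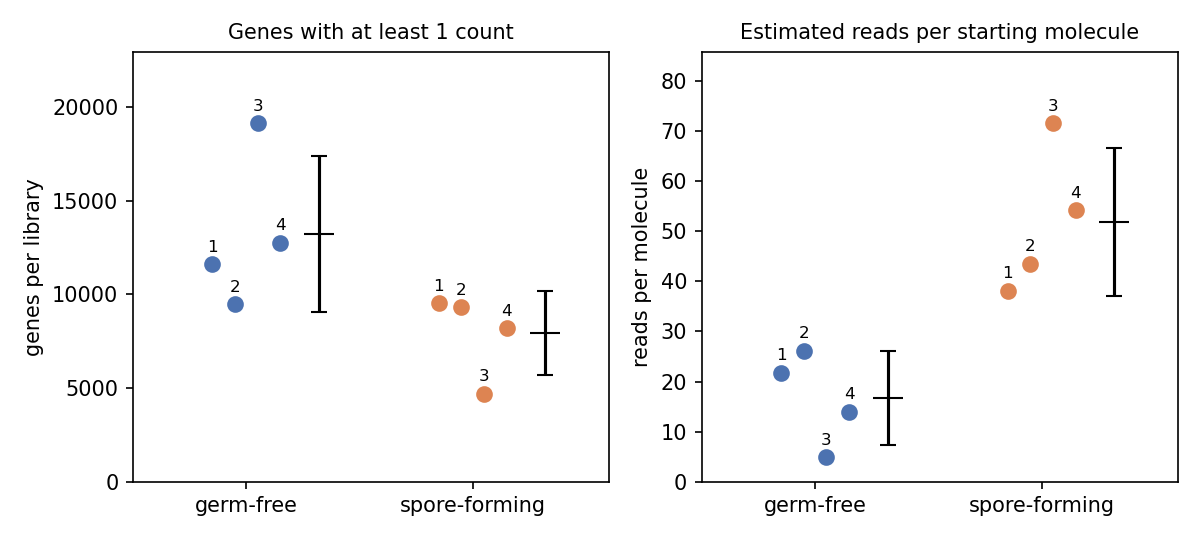
Genes with at least 1 count (left) and estimated reads per starting molecule (right) in each library, labelled by replicate number, with the group mean and SD as a bar beside the points (n = 4 per group). Reads per molecule ranged from 4.91 to 26.2 in germ-free and from 38.2 to 71.5 in spore-forming libraries.

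Between the groups, the smallest p belonged to Cyp2c55 (ENSMUSG00000025002), a cytochrome P450 that oxidises fatty acids and xenobiotics. It stood at 49.6 ± 16.7 CPM in germ-free and 341 ± 138 CPM in spore-forming libraries (SD, n = 4 each), a log2 fold change of 2.78 (SE 0.39), with all 4 spore-forming libraries above all 4 germ-free libraries. Its edgeR quasi-likelihood adjusted p of 0.0705 did not pass the threshold. No gene of 9848 tested passed in either direction by edgeR, while 361 had an unadjusted p under 0.05, of which 75 were higher and 286 lower in spore-forming libraries and 492 would be expected by chance. DESeq2 called 79 genes, of which 60 were at 0 throughout 1 group, and limma-voom called 3.

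Among the 10 genes with the smallest p, none of which passed the adjustment, Nr1d1 (ENSMUSG00000020889), a repressor of the circadian clock, was the other with a higher mean in spore-forming libraries. Its level was 276 ± 41.6 CPM against 109.5 ± 29.5 CPM in germ-free libraries, a log2 fold change of 1.33 (SE 0.31). Lower means were found for Krt19 (ENSMUSG00000020911), an epithelial keratin, at 165 ± 48.0 against 687 ± 323 CPM (log2 fold change -2.06, SE 0.36), and Slc13a1 (ENSMUSG00000029700), a sodium-sulfate cotransporter, at 373 ± 113 against 1059 ± 127 CPM (-1.51, SE 0.29). The tetraspan membrane proteins Tm4sf20 (ENSMUSG00000026149) and Tm4sf4 (ENSMUSG00000027801) had log2 fold changes of -1.83 (SE 0.36) and -1.94 (SE 0.45), and Arf6 (ENSMUSG00000044147), a small GTPase of membrane traffic, one of -1.02 (SE 0.25). In each of these genes the libraries of one group lay wholly above those of the other. Their edgeR adjusted p was 0.306 for Krt19 and 0.482 for Nr1d1, Slc13a1, Tm4sf20, Tm4sf4 and Arf6.

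The remaining 3 of the 10, the chaperone gene Hsp90aa1 (ENSMUSG00000021270), the histone gene Hist1h4d (ENSMUSG00000061482) and Gmds (ENSMUSG00000038372), an enzyme of GDP-fucose synthesis, had no counts in any spore-forming library. In germ-free libraries Hsp90aa1 stood at 38.1 ± 14.5 CPM, Hist1h4d at 37.9 ± 18.2 CPM and Gmds at 35.4 ± 34.4 CPM (SD, n = 4). The limits that 3 estimated molecules set in the 4 spore-forming libraries are 21.9, 24.6, 159.8 and 37.6 CPM. The means of all 3 genes exceed those of spore-forming replicates 1 and 2. The limits are not TMM-scaled, so the order is uncertain for replicate 4, whose limit lies near the means of Hsp90aa1 and Hist1h4d. These limits are estimates for each library alone and cover counting error only, and none was set for the libraries together. Absence therefore stays uncertain and no fold is given. Of the 286 genes lower at an unadjusted p under 0.05, 160 were likewise at 0 in all 4 spore-forming libraries, and Hist1h4d belongs to a family of near-identical histone genes.

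**Figure D2:**
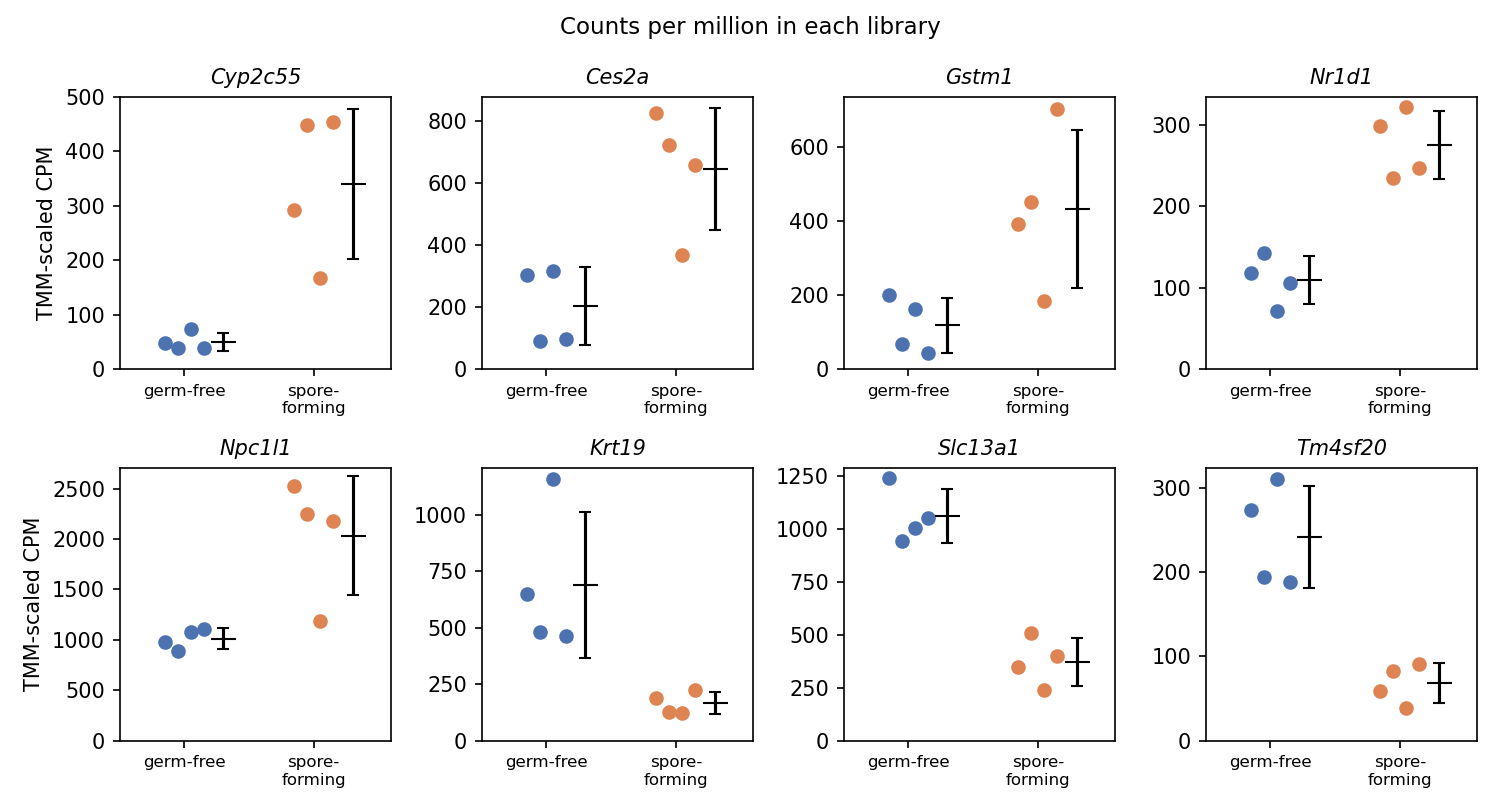
TMM-scaled CPM of 8 genes in each library of the germ-free and spore-forming groups, with the group mean and SD as a bar beside the points (n = 4 per group). Cyp2c55 ranged from 38.5 to 73.9 CPM in germ-free and from 167 to 454 CPM in spore-forming libraries, while Krt19 lay between 464 and 1155 CPM in germ-free and between 124 and 223 CPM in spore-forming libraries.

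The list of xenobiotic metabolism holds Cyp2c55 and other enzymes of detoxification. Adjusted over the list alone, 3 of its 44 tested members passed in the edgeR test, all with higher levels in spore-forming libraries, against 0 over all genes tested. Beside Cyp2c55 (edgeR p adjusted over the list alone 0.000315) these were Ces2a, a carboxylesterase, at 644 ± 197 against 203 ± 125 CPM (log2 fold change 1.67, SE 0.44), and Gstm1, a glutathione transferase, at 432 ± 213 against 119 ± 74.8 CPM (1.86, SE 0.51), both at 0.0424. Fmo5, a flavin monooxygenase, went the other way, with 447 ± 142 against 769.5 ± 162 CPM and an edgeR p adjusted over the list alone of 0.178. As a set, 18 members were higher and 26 lower, and the list did not pass camera (adjusted p = 0.0874). In the circadian list of 16 tested genes, 1 passed when adjusted over the list alone, Nr1d1 (edgeR, 0.0115). The circadian list had a camera adjusted p of 0.595.

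A total of 6 of the 39 tested lists passed camera. The cytosolic ribosomal proteins were lower in spore-forming libraries in 74 of 74 tested members, with a median log2 fold change of -1.63 against -0.26 over all tested genes (camera adjusted p = 3.87e-05 at the preset correlation, but adjusted p = 0.865 with an estimated correlation). Rps14 had a log2 fold change of -2.05 (SE 0.70) and Rps24 one of -2.53 (SE 1.11), and neither passed singly; without germ-free replicate 3 they were -1.26 and -1.36. The nuclear-encoded genes of oxidative phosphorylation were lower in 72 of 75 members, with a median of -0.67 (camera adjusted p = 0.0175, but adjusted p = 0.865 with an estimated correlation). Ndufv1, a subunit of complex I, stood at 81.3 ± 24.9 against 180.1 ± 47.1 CPM. Detection was lower as well, since 92.1% of the ribosomal protein genes had counts in germ-free against 68.8% in spore-forming libraries, and 96.7% against 81.6% of the oxidative phosphorylation genes. Much of this gap came from spore-forming replicate 3. Without it the difference over both lists together was -6.91 instead of -19.2 percentage points, while the ribosomal protein median was still -1.54. Without germ-free replicate 3, the library with the most detected genes, the medians of the ribosomal protein and oxidative phosphorylation lists were -0.68 and -0.41 and the camera adjusted p was 0.417 and 0.589. The oxidative phosphorylation call was also lost without germ-free replicate 1 (camera adjusted p = 0.287) and without spore-forming replicate 1 (0.175), 2 (0.0548) or 3 (0.128), the median without the last being -0.43. With a surrogate variable neither list passed (camera adjusted p = 0.751 and 0.976), nor without replicate 3 of both groups (0.668 and 0.949), and with a block on the replicate number oxidative phosphorylation did not (0.243).

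The markers of B and plasma cells were lower in 4 of 4 tested members, with a median log2 fold change of -2.68 (camera adjusted p = 0.0123, but adjusted p = 0.865 with an estimated correlation). Igkc, an immunoglobulin light chain, stood at 115 ± 142 CPM in germ-free libraries and had counts in 1 spore-forming library, and Igha, the IgA heavy chain, stood at 252 ± 281 against 72.4 ± 93.1 CPM (SD, n = 4 each). The other members, Sdc1, a surface gene, and Jchain, which joins IgA, had counts in 1 and 2 spore-forming libraries. Across germ-free replicates 1 to 4 Sdc1 was more even (34.7, 46.3, 73.5 and 45.6 CPM) than Igkc (98.6, 33.2, 320 and 6.75 CPM). Whether Sdc1 marks plasma cells in these libraries was not tested. Of the list, 43.8% was detected in germ-free against 12.5% in spore-forming libraries. Without germ-free replicate 3 the log2 fold change was -4.35 instead of -5.61 for Igkc and -0.90 instead of -1.80 for Igha, with a list median of -1.88, and without spore-forming replicate 1 neither Igkc nor Sdc1 had counts in that group. This direction was not particular to these cells. Score differences on the log2 scale were -1.64 for macrophage, -1.41 for T cell, -2.43 for neutrophil and mast cell and -1.13 for fibroblast markers, but also -1.55 for Paneth, -1.40 for enteroendocrine and -1.31 for tuft cell markers of the epithelium, against -0.42 for smooth muscle and -0.64 for endothelial markers, of which 4 of 6 members were higher in the fit. None of these scores passed (smallest adjusted exact permutation p = 0.3). The list did not pass without spore-forming replicate 2 (camera adjusted p = 0.186), without a filter (0.0815), with limma-voom (0.236), with a surrogate variable (0.0577) or without replicate 3 of both groups (0.0757).

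The other 3 called lists were higher in spore-forming libraries relative to all tested genes, whose median was below 0, and each had an adjusted p = 0.865 with an estimated correlation. Mitochondrially encoded transcripts were higher in 7 of 10 members, with a median log2 fold change of 0.18 (camera adjusted p = 0.00516), mt-Co1 being at 12125 ± 2798 against 9387 ± 2035 CPM. Genes of the unfolded protein response were higher in 15 of 23 members, with a median of 0.31 (camera adjusted p = 0.00911), among them Hyou1, a chaperone of the endoplasmic reticulum, at 252 ± 60.9 against 110.3 ± 36.3 CPM, and Dnajb11 at 109 ± 40.6 against 60.4 ± 20.2 CPM. Carbohydrate digestion and transport genes were higher in 14 and lower in 15 members, with a median of -0.00 and a camera adjusted p of 0.0222, so this call reflects their position against the lower median of all genes; the sugar transporters Slc5a9 and Slc2a7 had log2 fold changes of 0.83 (SE 0.39) and 0.62 (SE 0.32). Among genes counted in all 8 libraries the mitochondrial and carbohydrate lists did not pass (camera adjusted p = 0.325 for each). After scaling to molecules the camera adjusted p was 0.124 for the mitochondrial, 0.0762 for the unfolded protein and 0.0686 for the carbohydrate list, and with a surrogate variable it was 0.373 for the mitochondrial list. It was 0.0840 for the mitochondrial list without germ-free replicate 4 and 0.0878 for the unfolded protein list without spore-forming replicate 4. For the carbohydrate list it was 0.0935 without germ-free replicate 2, 0.0922 without germ-free replicate 4, 0.179 without spore-forming replicate 2 and 0.0878 without spore-forming replicate 4. None of the 6 calls held in the directional fry test. Without regard to direction, fry called 2 lists, immediate early and heat shock genes (adjusted p = 0.000387) and the circadian list (0.0366). In the first of these, Hsp90aa1 and Egr1 had no counts in any spore-forming library, where absence is uncertain, and the log2 fold changes of the other members lay between -1.08 and 0.98.

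**Figure D3:**
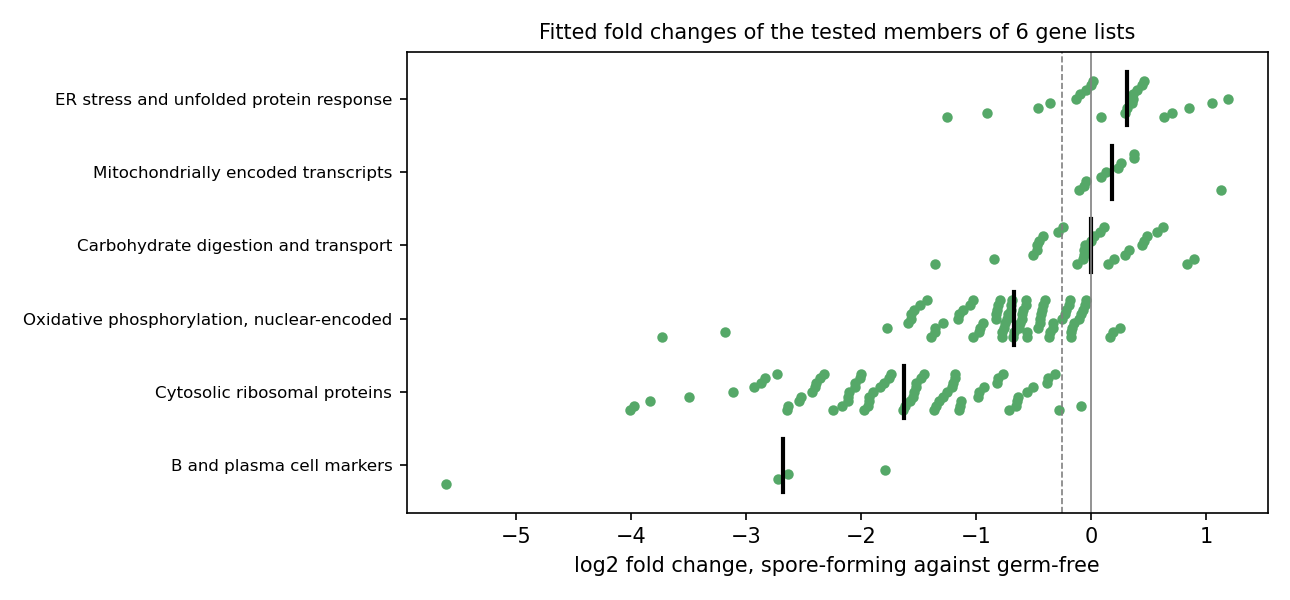
Fitted log2 fold change (x axis) of each tested member of the 6 gene lists past the camera threshold (y axis), 1 point per gene, with the list median as a black bar, 0 as a solid line and the median of all tested genes, -0.26, as a dashed line. The ribosomal protein points lie below 0 in 74 of 74 genes.

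Apart from carbohydrate digestion and transport, lists for nutrient absorption and lipid metabolism did not pass camera. Lipid absorption genes were higher in 5 and lower in 28 members (camera adjusted p = 0.387). In that list the cholesterol transporter Npc1l1 stood at 2034 ± 587 against 1012 ± 103 CPM in germ-free libraries (log2 fold change 1.01, SE 0.29), the fatty acid binding protein Fabp2 at 1374 ± 751 against 4488 ± 2208 CPM (-1.71, SE 0.51) and Dgat2, which makes triglyceride, at 902 ± 291 against 1630 ± 399 CPM. Peptide and amino acid absorption genes were higher in 9 and lower in 24 members (camera adjusted p = 0.271), with Naaladl1 at 882 ± 112 against 529 ± 129 CPM and Slc36a1 at 593 ± 373 against 302 ± 63.9 CPM. Iron and micronutrient genes were higher in 6 and lower in 15 (camera adjusted p = 0.474), with the metallothionein Mt1 at 12.1 ± 8.92 against 93.1 ± 69.5 CPM and the transferrin receptor Tfrc at 12.2 ± 9.81 against 82.6 ± 77.8 CPM. Fatty acid oxidation genes were higher in 7 and lower in 22 (camera adjusted p = 0.578), cholesterol synthesis genes in 3 and 18 (0.172), fatty acid synthesis genes in 5 and 6 (0.702) and bile acid genes in 5 and 3 (0.310). No member of these 7 lists passed when adjusted over the list alone in the edgeR test.

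Genes that respond to microbes showed no list past the camera threshold. Interferon response genes were higher in 9 and lower in 27 members (camera adjusted p = 0.0597), with Apol9b at 27.1 ± 3.52 against 80.2 ± 19.2 CPM and Irgm2 detected in 1 spore-forming and 4 germ-free libraries. Apol9b has a close paralog, so its counts are uncertain. Antimicrobial defence genes were higher in 4 and lower in 11 (camera adjusted p = 0.771). The lectin gene Reg3g stood at 10.8 ± 6.05 CPM in germ-free libraries and had no counts in spore-forming libraries, a level below their 3-molecule limits, while Reg3b stood at 66.2 ± 20.2 and 25.1 ± 19.1 CPM and Lypd8 at 434 ± 292 and 201 ± 123 CPM. Antigen presentation genes of class II were higher in 3 and lower in 4 (camera adjusted p = 0.578), with Cd74 at 29.1 ± 22.8 against 116 ± 41.1 CPM, and those of class I were higher in 12 and lower in 12 (0.310), with H2-Q1, which has close paralogs, at 379.9 ± 128 against 498 ± 102 CPM. Innate sensing genes were higher in 7 and lower in 9 (camera adjusted p = 0.621), IgA transport and retinoid genes in 1 and 14 (0.172), mucosal glycosylation genes in 7 and 11 (0.933) and junction genes in 10 and 14 (0.301). No member of these 8 lists passed when adjusted over the list alone in the edgeR test.

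Cell type markers and RNA quality lists were lower in spore-forming libraries in 19 of 21 scores, and none passed (smallest adjusted exact permutation p = 0.3). The enterocyte score was 11.16 ± 0.53 in germ-free and 10.63 ± 0.74 in spore-forming libraries on the log2 scale (SD, n = 4 each; exact permutation p = 0.343). Scores of immediate early genes, 5.84 ± 0.06 and 4.80 ± 0.76, and of macrophage markers, 3.88 ± 0.58 and 2.24 ± 1.53, separated the groups (each exact permutation p = 0.0286). Both scores hold members with no counts in any spore-forming library, Hsp90aa1 and Egr1 in the first and C1qc in the second. Part of each difference therefore rests on genes whose absence is uncertain, and the scores without them were not compared. By camera, the adjusted p was 0.621 for enterocyte, 0.195 for villus tip, 0.271 for villus bottom, 0.621 for goblet, 0.611 for Paneth, 0.621 for enteroendocrine, 0.595 for tuft and 0.854 for crypt stem cell markers. For cells outside the epithelium it was 0.310 for T cell and for macrophage markers, 0.764 for fibroblast, 0.621 for smooth muscle and 0.771 for endothelial markers. The cell cycle, immediate early and nuclear-retained lists had a camera adjusted p of 0.301, 0.346 and 0.483. Single members passed the edgeR test when adjusted over the list alone in 5 of these lists, namely Hsp90aa1, Tcrg-C1, C1qc, Kit and Hhip, each with no counts in any spore-forming library. In germ-free libraries Tcrg-C1, C1qc, Kit and Hhip stood at 14.3, 8.95, 14.2 and 12.1 CPM. These levels lie below 21.9 CPM, the lowest limit that 3 estimated molecules set in a single spore-forming library. No limit was set for the 4 libraries together, so absence stays uncertain. Neutrophil and mast cell markers had 2 tested members, Kit and Siglecf, and were not tested as a set; nor were erythrocyte markers with Hbb-bs or pancreatic acinar markers with Clps as the 1 tested member, and enteric neuron and Brunner gland markers had 0.

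Of the 3709 tested genes with counts in all 8 libraries, 46.5% had a positive log2 fold change. Among these, 73 were higher and 97 lower at an unadjusted edgeR p under 0.05. The groups did not overlap in 624 genes, 6.34% of those tested against 2.86% by chance, with 104 higher and 520 lower in spore-forming libraries. Genes in a library vary together, so this share is not a test.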

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

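Of the tests in this part, the one on starting molecules, the one on genes counted in all 8 libraries, the one without germ-free replicate 3 and the reading of each list alone without spore-forming replicate 3 were chosen only after the result was seen, as was the requirement that no single library decide the test on cell types.

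A single library lay far from the other 3 of its group in 16 of 190 sets of values, against about 10 by chance, or 1 in 20. That rate does not hold where the other 3 libraries are tied, mostly at 0, since any other value is then flagged. The excess over 10 is therefore not evidence of unusual libraries. In germ-free replicate 3, 26.5% of detected genes had 1 to 9 counts, against at most 5.23% in the other 3, and Rps24 stood at 257 CPM against at most 67.8 CPM. In germ-free replicate 2, 79.6% of ribosomal protein and oxidative phosphorylation genes were detected against 99.3% in the others, Dgat2 was low at 1037 CPM and Slc5a9 high at 138 CPM. Spore-forming replicate 3 detected 38.2% of those genes, reached even odds of detection only at 36.9 CPM, and was low in the villus bottom score, 3.67, and in Arg2, 82.6 CPM. Spore-forming replicate 4 was high in the neutrophil and mast cell score, 2.30, and spore-forming replicate 2 was high in the erythrocyte score, 3.78. These values rest on Siglecf and Hbb-bs, which had no counts in the other spore-forming libraries. Spore-forming replicate 1 was high in Lypd8, 383 CPM, Igkc, 8.81 CPM, Sdc1, 29.9 CPM, Irgm2, 7.47 CPM, and Aldh1a3, 1.34 CPM, the last 4 being genes with no counts in the other spore-forming libraries.

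Fewer genes were detected in the spore-forming libraries, which fewer counts do not account for as a whole, since 80.2% of the difference remained after thinning to equal totals. Few starting molecules, each amplified to many reads, cannot be told apart from other causes, since detecting more low genes lowers the 10th percentile of nonzero counts whatever the cause. That percentile went against genes detected with Spearman's rho = -0.929 (exact permutation p = 0.00223, adjusted 0.00223) and Pearson's r = -0.955 (exact permutation p = 9.92e-05, adjusted 0.000198; n = 8), and r was -0.939 without germ-free replicates 3 and 4 or -0.971 without germ-free and spore-forming replicate 3. A narrower capture of cell types cannot be told apart either; by the rule written beforehand it would have been argued against, because detection of genes that all cell types use differed by -19.2 percentage points with a pooled SD of 18.8, but by -6.91 with an SD of 7.02 without spore-forming replicate 3. A difference in RNA content brought by the bacteria or the parents stays open and was not tested.

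Ribosomal protein and oxidative phosphorylation lists were lower in the spore-forming group. Transcript length is argued against as the whole cause, since genes matched on length and abundance were shifted less. Both medians, -1.63 and -0.67, lay at percentile 0 of 10000 matched random lists, whose central range was -0.53 to -0.11 and -0.47 to -0.12. The draws were independent while genes of these lists vary together (estimated correlation 0.54 and 0.49), so the percentiles do not measure chance. Among genes counted in all 8 libraries, 14 and 34 members remained, with medians of -0.79 and -0.61, again at percentile 0 of abundance-matched lists. This cannot decide on chance loss of genes, since the restriction leaves out the members on which such loss acts. The library with the most detected genes may carry the calls: without germ-free replicate 3 the median went from -1.63 to -0.68 for ribosomal proteins (quartiles -1.25 and -0.16) and from -0.67 to -0.41 for oxidative phosphorylation (quartiles -0.79 and -0.05), each with 58 members still lower, and the camera adjusted p was 0.417 and 0.589 (range over 22 alternatives 2.01e-12 to 0.865 and 2.86e-05 to 0.976). Spore-forming replicate 3, the library with the fewest detected genes, is argued against for ribosomal proteins, whose median without it was -1.54 (camera adjusted p = 6.36e-05), but cannot be told apart for oxidative phosphorylation, whose median was -0.43 (quartiles -0.83 and -0.23) and whose call was lost (0.128); the bacteria themselves also stay open.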

How the results depend on the processing

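Cyp2c55 was higher in spore-forming libraries under all 20 alternatives run (log2 fold change 2.59 to 3.26) and passed the threshold in 11 of them (adjusted p 4.13e-07 to 0.478). Over the named genes, 1160 comparisons kept their side of the threshold, 48 moved past it and 0 reversed. No named gene passed in the main fit, so no call could be lost. Keeping a side here only means staying short of the threshold, which says little about stability.

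The edgeR test called 0 genes. It called 1 gene, Cyp2c55, with DESeq2 size factors, with upper-quartile scaling and with 1 surrogate variable. Without a filter it called 5 higher and 22 lower genes. DESeq2 called 10 higher and 69 lower, and limma-voom with quality weights 2 higher (Cyp2c55, Npc1l1) and 1 lower (Slc13a1). Leaving out a library gave 0 to 1 in each direction, namely Cyp2c55 without germ-free replicate 3 (adjusted p = 0.0479) and Cyp2c55 (0.00535) and Ugt1a9 without spore-forming replicate 3. Settings chosen after seeing the data called 1 gene, Cyp2c55, among genes counted in all 8 libraries and again without replicate 3 of both groups, and 3 higher (Ces2a, Cyp2c55, Gstm1) and 5 lower (Cyp1a1, Krt19, Slc13a1, Tm4sf20, Ugt1a9) of 2551 genes after scaling to molecules. The cause was not tested.

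Of gene lists, 3 higher and 3 lower were called. Lower lists numbered 5 without a filter, 7 with DESeq2 and 0 with a surrogate variable, and 2 to 5 with a library left out, when higher lists numbered 1 to 5. Higher lists numbered 1 among genes counted in all 8 libraries, 6 (with 0 lower) without replicate 3 of both groups and 0 after scaling to molecules. An estimated correlation and fry called 0 lists either way. With a surrogate variable the camera statistic of oxidative phosphorylation changed sign (adjusted p = 0.976), although 40 of 75 members were lower with a median of -0.05. For carbohydrate digestion fry, which tests against no change rather than against other genes, gave the lower direction (0.920). The scores passed in 0 alternatives, which says nothing about stability, since the smallest exact p is 0.0286 before adjustment over 21 scores and 0.125 with a block on the replicate number.

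The replicate numbers did not pair the samples: deviations of same-numbered libraries correlated at 0.00798, -0.0612, -0.126 and -0.0139, and 0 of 4 exceeded 0.1. A block on the number called 0 genes (smallest adjusted p = 0.283) and 5 lists.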

Other observations

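The tests of Cyp2c55 with counts scaled to molecules and without replicate 3 of both groups were chosen only after the result was seen, and the genes in the next paragraph outside the Cyp2c family were picked after their values were seen.

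Other genes of drug metabolism went in different directions. Cyp1a1, a target of the aryl hydrocarbon receptor, stood at 393 ± 123 CPM in germ-free and 48.5 ± 67.9 CPM in spore-forming libraries (log2 fold change -3.01, SE 1.15; edgeR adjusted p = 0.994), and Ugt1a9, a glucuronosyltransferase, at 175 ± 39.5 and 13.1 ± 11.1 CPM (-3.72, SE 0.90; edgeR adjusted p = 0.482). In both genes all 4 germ-free libraries lay above all 4 spore-forming libraries, and spore-forming replicate 3 had no counts. Cyp2c29 stood at 564 ± 119 and 1007 ± 426 CPM, Cyp2c65 at 389 ± 133 and 296 ± 201 CPM and Cyp2c66 at 235 ± 68.4 and 324 ± 155 CPM (SD, n = 4 each), and none passed the edgeR test. Ugt1a9 shares exons with other Ugt1a genes, so its counts are uncertain.

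Cyp2c55 was higher in the spore-forming group without passing the adjustment. Reads shared with other Cyp2c genes are argued against, since the other 6 tested Cyp2c genes had a median log2 fold change of -0.13, with 0.83 as the highest, against 2.78 for Cyp2c55. In counts scaled to molecules Cyp2c55 passed (edgeR adjusted p = 0.000401, log2 fold change 2.80, SE 0.34), against 2.78 (SE 0.39) in the main fit. This cannot decide on chance loss of molecules. Dividing each library by a constant leaves the fold change nearly fixed in advance, and 2551 instead of 9848 genes were tested there. Library complexity cannot be told apart from the group, since reads per molecule did not overlap between the groups, with or without replicate 3 of both. Cyp2c55 also passed with a surrogate variable (edgeR adjusted p = 0.00585, log2 fold change 3.15, SE 0.34), which mainly marked spore-forming replicate 3. It passed again without replicate 3 of both groups (edgeR adjusted p = 0.00401, log2 fold change 3.26, SE 0.31). Its adjusted p over 20 alternatives ranged from 4.13e-07 to 0.478. Molecule numbers are estimates, and only 4.47 stood behind Cyp2c55 in spore-forming replicate 3 and 5.54 in germ-free replicate 2. A response to the bacteria and a difference in parents or litter stay open and were not tested apart.

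Splits of the 8 libraries into 4 and 4, of which there are 35, do not exclude chance for the genes at an unadjusted p under 0.05 or for the called lists. For genes past the threshold they cannot test it: the real count is 0, so 35 of 35 splits give as many, with 1 as the highest of the others. The 361 genes at an unadjusted p under 0.05 were matched or exceeded in 3 of 35 splits, with 549 as the highest other, and the 6 called lists in 11 of 35, with 13 as the highest other.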
